A study of Homo sapiens with 6 samples.

How the data were processed

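Small RNAs were sequenced from K562 cells (K562i in the sample titles) carrying dCas9-KRAB with a control guide (3 libraries) or a guide to CYRANO (3 libraries). Per the labels, the replicates were biological, RNAs of 18 to 32 nucleotides were selected from 5 micrograms of total RNA, and RNA integrity numbers were 9.9 to 10. Groups were taken from the treatment label of each library. The aligner, the miRNA annotation, the genome build and the rule for mismatches and shared reads are not given in the sources used here.

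The authors deposited 1 table with whole-number read counts per mature miRNA in each library. The submitters' processing notes name cutadapt and DESeq2 1.10. Per the file headers and the values, a further set of columns holds a normalized signal, the counts that the authors divided by 1 size factor per library. These factors were 0.409, 1.14 and 1.09 for the control guide and 1.26, 1.46 and 1.15 for the CYRANO guide. The deposited log2 fold changes and their standard errors are those of the authors' comparison, and whether they were shrunk is not given in the sources used here. The deposited p-value columns hold the authors' unadjusted and adjusted values, and the adjusted ones equal a Benjamini-Hochberg adjustment over their 1250 miRNAs. Another 2 columns of that comparison, a mean level and a test statistic, were not used. Everything printed is computed here from the counts unless the authors' deposited table is named.

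Library totals are the reads of the miRNAs in the table, from 465234 to 1654355, and not all reads sequenced. A floor of 3 reads was worth 6.45, 2.36 and 2.53 CPM in the control guide libraries and 2.10, 1.81 and 2.31 in the CYRANO guide libraries. Intervals and floors cover counting error and, in the fitted model, the spread between libraries, but reads amplified by PCR are not independent molecules. Libraries of a group differed from each other by more than sampling noise. The chi-square per degree of freedom was 7.34, 12.9 and 22.1 for pairs of control guide libraries. It was 3.49, 5.00 and 3.49 for pairs of CYRANO guide libraries, while the fitted model took the same spread for both groups. These values cannot tell repeats of 1 sample from biological replicates, which rest on the labels.

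Counts were tested with edgeR 4.0.16 in R 4.3.3. miRNAs were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and the quasi-likelihood test was followed by Benjamini-Hochberg adjustment with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic, and intervals are at 95%. CPM values are TMM-scaled, and shares are of the reads of the miRNAs in the table used here, with other miRNAs not analysed here. The ratio of miR-7-5p to miR-7-1-3p was compared on the log2 scale with a pseudocount of 1 read by an exact two-sided permutation test.

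Lists of miRNAs (17) were fixed before the data were examined: the miR-7 guide strand, the miR-7 passenger strands, miR-671, miRNAs with other degradation triggers, miR-17-92 and paralogs, let-7, erythroid, other blood lineages, non-blood tissues, miR-15/16, miR-181, miR-30, the miR-183, miR-96 and miR-182 cluster, 14q32, stress-responsive, Drosha-independent and 15q15. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, with the estimated correlation and with fry. List members without a row in the table used here, such as let-7a-5p, miR-21-5p and miR-7-2-3p, were not analysed here.

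The naming rule, also fixed before the data were examined, took the strands of miR-7 and miR-671 and up to 10 miRNAs past the threshold in each direction, filled up to 5 by the smallest unadjusted p. It also took the 2 most abundant members of each list and the 5 most abundant miRNAs. The tests, the naming rule, the lists and most alternatives were set before the data were examined. Alternatives set in advance were DESeq2 size factors, library totals alone, totals without miR-7-5p and the 5 most abundant miRNAs, no low-count filter, a mean of at least 100 reads, DESeq2 1.42.0, limma-voom, other thresholds, a replicate block, other pseudocounts and leaving out each library. Thinning to equal depth and removal of a GC trend were added after the data were seen.

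Hairpin positions and the GC content of each hairpin arm came from GENCODE release 29 on GRCh38, matched by miRNA name. Arm GC content stands in for that of the mature strand, whose sequence the table does not give. The miR-7-5p sequence was entered from general knowledge and found in the 3 annotated hairpins.

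The test was tried on simulated counts for the 397 miRNAs with the levels and depths of this comparison, over 10 simulations. Dispersion followed its fitted trend with level, the same in both groups, and no GC trend was put in. The changed miRNAs of each simulation were spread over 1.25-fold, 1.5-fold, 2-fold and 3.2-fold changes together, so recovery at each size rests on this mixture. With 200 miRNAs changed, the test recovered 45.1% of those at 1.25-fold, 78.6% at 1.5-fold, 96.3% at 2-fold and 99.6% at 3.2-fold, and 1.89% of calls were false. With 20 changed, recovery was 14.3%, 59.2%, 89.1% and 97.9%, and 3.91% of calls were false.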

Results

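Mature miRNAs were counted in 6 small-RNA libraries from K562 cells (labelled K562i in the sample titles), a human chronic myeloid leukemia line with erythroid features. The cells carried dCas9-KRAB, a cleavage-dead Cas9 joined to a transcriptional repressor domain, together with a guide RNA that directs it to CYRANO (3 libraries) or a control guide (3 libraries). CYRANO is a long noncoding RNA with a site for the miRNA miR-7, annotated as OIP5-AS1 on chromosome 15 from 41283990 to 41309737 on the plus strand (GRCh38). The libraries held 465234, 1273268 and 1185201 reads of the listed miRNAs with the control guide, and 1429429, 1654355 and 1296297 with the CYRANO guide. Of 2366 mature miRNAs listed, 1250 had at least 1 read, and the 397 with enough reads to be tested held 99.9% of the reads of every library. CYRANO itself lies outside the size class of these libraries, and its level was not analysed here.

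The comparison addressed which miRNAs changed when CYRANO was targeted, with miR-7 of first interest. miR-7-5p, the guide strand of miR-7, was 3.2-fold higher with the CYRANO guide (95% interval 2.78 to 3.68). Its read count scaled to a common library depth (CPM) was 1992 ± 342 (SD, n = 3) with the control guide and 6333 ± 350.2 (SD, n = 3) with the CYRANO guide. Each of the 3 CYRANO guide libraries, at 5934, 6474 and 6590 CPM, lay above each control guide library, at 2386, 1769 and 1823. As a share of the reads of all listed miRNAs, miR-7-5p went from 0.20% ± 0.028 to 0.628% ± 0.029 (SD, n = 3 each).

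The log2 fold change of miR-7-5p was 1.68 with a standard error of 0.0958, at an edgeR adjusted p of 1.31e-09. In the authors' deposited table it was 1.68 with a standard error of 0.102 and an adjusted p of 1.57e-57. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 libraries against 3 allow. The per-library values rested on 1080, 2287 and 2227 reads with the control guide and on 8491, 10623 and 8390 reads with the CYRANO guide.

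**Figure D1:**
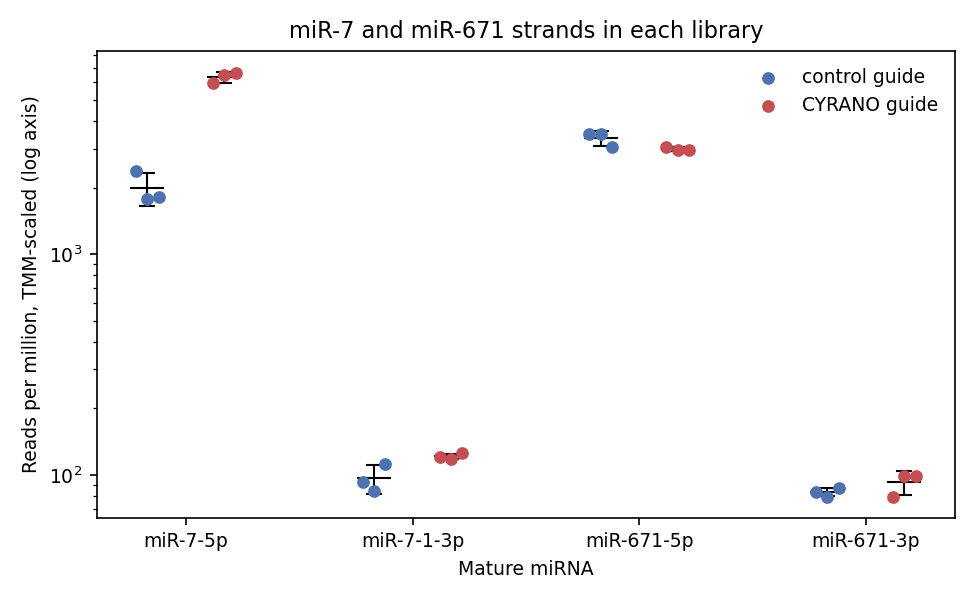
CPM (TMM-scaled, log axis) of the miR-7 and miR-671 strands in each of the 3 control guide libraries (blue) and 3 CYRANO guide libraries (red), with the mean (wide bar) and SD (capped line) of each group. miR-7-5p lies between 1769 and 2386 with the control guide and between 5934 and 6590 with the CYRANO guide.

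The human genome holds 3 annotated miR-7 hairpins, and the 23-base mature sequence TGGAAGACTAGTGATTTTGTTGT occurs in all 3, so reads of miR-7-5p cannot be assigned to 1 of them. In GENCODE release 29 (GRCh38), MIR7-1 lies on chromosome 9 from 83969748 to 83969857 on the minus strand, inside HNRNPK, a gene for an RNA-binding protein. It falls in an intron of 4 of the 5 coding HNRNPK transcripts that span it and touches an exon of the other. MIR7-2 lies on chromosome 15 from 88611825 to 88611934 on the plus strand, with no annotated host gene on that strand. MIR7-3 lies on chromosome 19 from 4770670 to 4770779 on the plus strand, in an intron of MIR7-3HG. The 8-base sequence GTCTTCCA, which pairs with bases 2 to 8 of miR-7-5p and adds an A, occurs in 2 of the 10 annotated OIP5-AS1 transcripts. Both occurrences lie in exon 4 of 4. They differ in the bases before the 8-base site. In the stretch that starts at 41300572, these bases also hold an unbroken complement of the end of miR-7-5p, up to its last base. The stretch that starts at 41298409 holds no such run, so the sites are not equivalent in sequence. Binding of miR-7-5p to either was not tested. The first ends the stretch CTTCAGGGTTTAAAAAAAATGTCTTCCA at chromosome 15, 41298409 to 41298436, in 2 transcripts. The other ends AGAACAACAAAATCACCAATGTCTTCCA at 41300572 to 41300599, in 1 transcript.

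miR-7-1-3p, the passenger strand of the MIR7-1 hairpin, did not pass the test, with a log2 fold change of 0.32 (SE 0.131, 95% interval 0.04 to 0.60, edgeR adjusted p = 0.392). It was counted at 96.4 ± 14.3 CPM with the control guide and 121.1 ± 3.64 with the CYRANO guide (SD, n = 3 each). The ratio of miR-7-5p to miR-7-1-3p was 21.0 ± 4.73 with the control guide and 52.3 ± 3.01 with the CYRANO guide (SD, n = 3 each). The log2 ratio was higher by 1.35 (SE 0.191) with the CYRANO guide, a 2.55-fold difference, and the groups did not overlap (exact two-sided permutation p = 0.1, the smallest possible). The log2 fold change of miR-7-1-3p was 0.20 without control 2 and 0.44 without control 3, and it passed the threshold in neither case. The passenger strand of MIR7-2 was not analysed here.

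miR-671-5p, which directs cleavage of the circular RNA Cdr1as, had a log2 fold change of -0.16 (SE 0.0717, edgeR adjusted p = 0.432), and miR-671-3p one of 0.15 (SE 0.138, adjusted p = 0.740). Without control guide library 3, miR-671-5p passed the threshold at -0.26. The MIR671 hairpin lies on chromosome 7 from 151238421 to 151238538 on the plus strand, inside CHPF2, and touches an exon of at least 1 annotated transcript. With both strands of miR-671 taken as a list, 0 of 2 passed over all miRNAs tested and 0 when adjusted over the list alone (1 without control 3).

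miR-7-5p was the single miRNA past an edgeR adjusted p of 0.05, with 1 higher and 0 lower. At an unadjusted threshold of 0.05 there were 26 higher and 16 lower, 42 in all, where chance gives 19.85 of 397. DESeq2's Wald test on the same counts passed 3, adding miR-1908-5p and miR-3194-5p as lower, and limma-voom passed 1. The authors' deposited table, over 1250 miRNAs, holds 1 past an adjusted p of 0.05 and 22 at an unadjusted 0.05. Those 1250 include the 853 with too few reads to be tested here, so the 22 cannot be set against the 42 of 397. The authors' p-values were not counted among the 397 alone. Leaving out 1 library moved the count of 1 to 3 without control 1 (miR-21-3p and miR-223-5p added), to 2 without control 2 (miR-29b-3p added) and to 7 without control 3. That last set added miR-15b-5p as higher and miR-1908-5p, miR-3194-5p, miR-33b-5p, miR-378a-5p and miR-671-5p as lower. Without CYRANO guide library 1 the count was 2 (miR-3194-5p added). miR-21-3p, miR-33b-5p and miR-378a-5p are named because their values were seen, outside the naming rule.

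No other tested miRNA had a log2 fold change above 1 in size, and the range was -0.94 to 0.92. Of the 69 other miRNAs with a mean of at least 1000 CPM, log2 fold changes ran from -0.23 to 0.31, and the 95% interval of all 69 lay within 1.5-fold. Over all 396 others, the interval lay within 1.5-fold for 245 and within 2-fold for 360. For the remaining miRNAs a change of that size was not excluded at this depth.

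**Figure D2:**
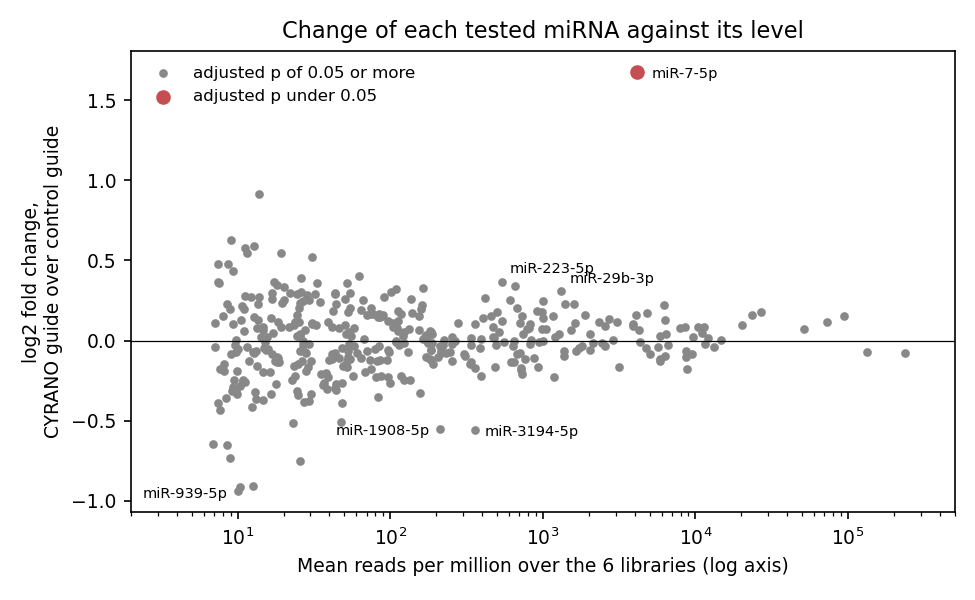
log2 fold change (CYRANO guide over control guide) of each of the 397 tested miRNAs against its mean CPM over the 6 libraries (log axis), with the miRNA past an adjusted p of 0.05 in red. miR-7-5p stands at 1.68, and every other point lies between -0.94 and 0.92.

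The miRNAs next in rank did not pass the test. On the higher side, miR-223-5p, from a myeloid miRNA hairpin, had a log2 fold change of 0.37 (edgeR adjusted p = 0.182) and miR-29b-3p one of 0.31 (adjusted p = 0.261). miR-454-3p stood at 0.26 and miR-301a-3p at 0.27, and both hairpins lie in SKA2 introns on chromosome 17. On the lower side, miR-1908-5p stood at -0.55 (adjusted p = 0.116) and miR-3194-5p at -0.56 (adjusted p = 0.182). The miR-1908 hairpin lies inside FADS1 and touches an exon of at least 1 annotated transcript. miR-939-5p stood at -0.94 on a mean of 10.1 CPM, miR-23a-5p at -0.32 and miR-146b-5p at -0.17. In 16.4% of the 397 miRNAs the groups did not overlap, 37 higher and 28 lower, where chance gives 10%.

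Across the tested miRNAs as a set, the differences went with base composition. Across the 397 miRNAs, the log2 fold change and the GC content of the hairpin arm had a Spearman rho of -0.311 (permutation p = 1e-04, the smallest that the permutations drawn can give), across miRNAs, which are not independent replicates. Median arm GC content was 44.2% for the 25 higher miRNAs at an unadjusted 0.05 without miR-7-5p, 59.5% for the 16 lower and 50.0% for all tested. Without control guide library 3, rho was -0.176. After removal of a linear GC trend from each library, miR-7-5p had a log2 fold change of 1.63 (SE 0.0981) and was again the single miRNA past the threshold. In that fit miR-223-5p stood at 0.41, further from 0 than in the reported fit, while miR-29b-3p stood at 0.24 and miR-1908-5p at -0.45, both nearer to it.

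The 5 most abundant of the listed miRNAs took 59.0% ± 1.41 of their reads with the control guide and 58.2% ± 0.105 with the CYRANO guide (SD, n = 3 each), and none of them passed the test. miR-19b-3p went from 24.4% ± 0.617 to 22.9% ± 0.426 of reads (log2 fold change -0.07), and miR-92a-3p from 13.6% ± 0.798 to 12.8% ± 0.216 (-0.07). miR-20a-5p went from 8.92% ± 0.307 to 9.80% ± 0.074 (0.16), miR-17-5p from 6.98% ± 0.089 to 7.47% ± 0.210 (0.12), and miR-142-3p, a miRNA of blood cells, from 5.06% ± 0.891 to 5.26% ± 0.157 (0.07). The miR-17-92 cluster and its paralogs promote proliferation. The 10 of 13 members analysed here made up 57.3% ± 1.16 and 56.4% ± 0.099 of the reads of listed miRNAs, and miR-18a-5p, miR-19a-3p and miR-18b-5p were not analysed here. Of their 8 tested members, 0 passed over all miRNAs and 0 when adjusted over the list alone (1 without control 1).

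Erythroid miRNAs were abundant in this line, with miR-451a at 27018 and miR-486-5p at 14598 CPM. None of the 5 passed over all miRNAs tested, and 2 did when adjusted over the list alone, miR-451a at 0.18 and miR-486-3p at 0.23 on the log2 scale. That count of 2 was 0 without control 1, CYRANO guide library 1 or CYRANO guide library 3, 1 without CYRANO guide library 2 and 3 without control 2, and miR-451a stood at 0.10 without control 1. The list had a median of 0.14, with 4 members above 0 (miR-486-5p, at 0.00, fell below 0 under each of the 3 other scalings), and an adjusted camera p of 0.108 (0.633 with an estimated correlation). Among miRNAs of other blood lineages, 0 of 3 passed over all or when adjusted over the list alone, with miR-142-3p at 0.07 (-0.11 without control 3, 0.17 without control 1) and miR-223-3p at -0.02. The lymphoid miR-150-5p and miR-155-5p had 8 reads each over the 6 libraries, and miR-146a-5p had 59. Of the markers of non-blood tissues, 0 of 5 tested passed over all or when adjusted over the list alone (1 of the latter without control 3). In that list as endothelial, miR-126-3p was at 8636 CPM, and miR-9-5p, in it as neuronal, at 941.9, so neither marks non-blood tissue here. Liver miR-122-5p and neuronal miR-124-3p had 33 and 23 reads in total.

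The miR-15/16 family, which restrains the cell cycle, had all 5 tested members above 0, with a median log2 fold change of 0.17. miR-16-5p stood at 0.16 and miR-15a-5p at 0.08, and at 0.12 and 0.01 after removal of the GC trend. Without control 3, miR-15a-5p stood at -0.04. None passed over all miRNAs or when adjusted over the list alone (2 of the latter without control 3), and the list had an adjusted camera p of 0.0752 (adjusted p = 0.519 with an estimated correlation). The cluster of miR-183, miR-96 and miR-182 had all 3 members above 0, with a median of 0.19. None passed over all miRNAs, miR-96-5p at 0.22 passed when adjusted over the list alone, and the list had an adjusted camera p of 0.0818 (adjusted p = 0.633 with an estimated correlation). Adjusted over the list alone, the count was 0 without control 1, CYRANO guide library 2 or CYRANO guide library 3, and 3 without control 3. Of the 10 lists with at least 3 tested members, 0 passed an adjusted p of 0.05 by limma's camera, 3 were at an unadjusted 0.05, and 0 passed with an estimated correlation or by fry. Without control 2, the erythroid and miR-15/16 lists passed camera (2 lists). Without control 3, and without CYRANO guide library 1, the miR-183, miR-96 and miR-182 cluster did (1 list each). Across all tested miRNAs the log2 fold change also went with arm GC content, at the rho of -0.311 given above. Removal of the GC trend left miR-183-5p at 0.17, miR-96-5p at 0.19 and miR-182-5p at 0.15. In the miR-15/16 family, miR-15b-5p then stood at 0.12, miR-195-5p at 0.23 and miR-497-5p at 0.42. Among erythroid miRNAs, miR-451a then stood at 0.12 and miR-486-3p at 0.30. The lists themselves were not tested with the trend removed.

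**Figure D3:**
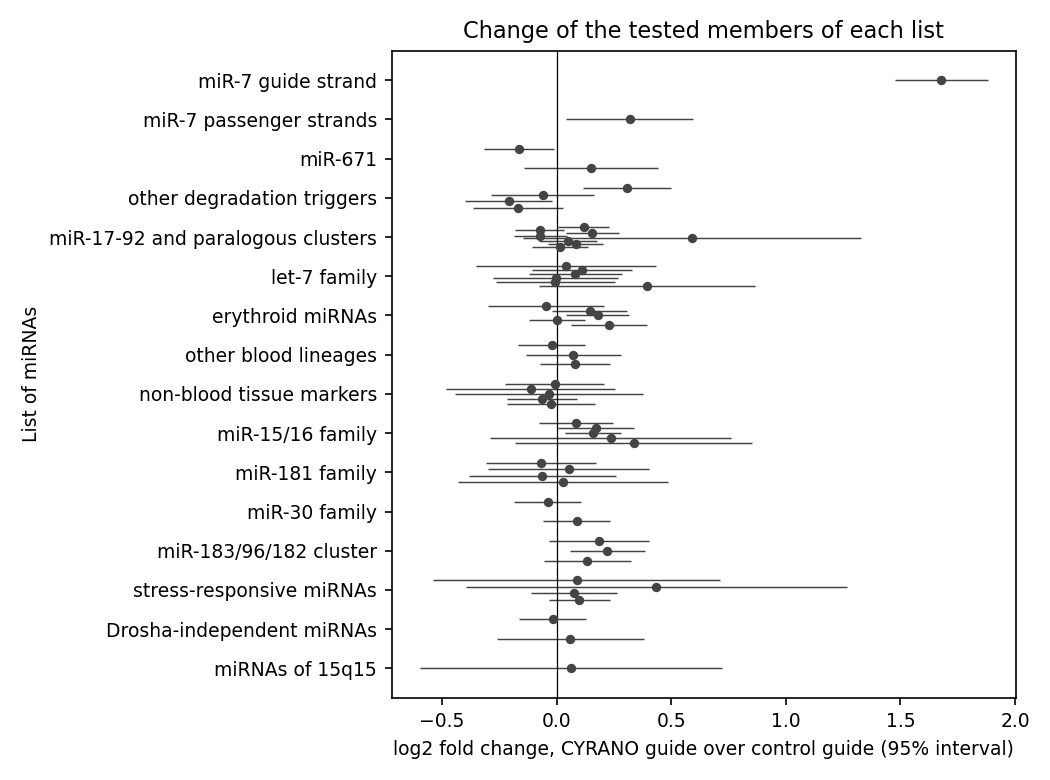
log2 fold change (CYRANO guide over control guide) of the tested members of each list, as points with 95% intervals (lines). The miR-7 guide strand stands at 1.68, and the list of other degradation triggers holds the 4 tested miRNAs with a described trigger other than CYRANO.

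Other miRNAs for which a degradation-inducing target has been described gave 0 of 4 past the threshold over all miRNAs. miR-29b-3p, at 0.31, passed when adjusted over the list alone, and without control 2 it passed over all miRNAs at 0.43. The list-alone count was 0 without control 1 or CYRANO guide library 3, and 3 without control 3 or CYRANO guide library 1. miR-221-3p stood at -0.21 and miR-222-3p at -0.17, and the list's median was -0.12. Without CYRANO guide library 2, miR-221-3p stood at -0.13 and the direction given by camera turned from lower to higher. The let-7 family, regulators of differentiation, had 0 of 6 past the threshold over all or when adjusted over the list alone, with let-7e-5p at 0.11 (0.01 without control 1, 0.23 without control 3) and let-7f-5p at 0.08 (0.02 without control 2, 0.18 without control 3). Likewise 0 of 4 passed in the miR-181 family (miR-181a-5p at -0.07, miR-181c-5p at -0.06), and 0 of 2 in the miR-30 family (miR-30e-5p at 0.09, miR-30d-5p at -0.04). Among stress-responsive miRNAs 0 of 4 passed, with miR-22-3p at 0.10 and the hypoxia-induced miR-210-3p at 0.07. Among miRNAs made without Drosha 0 of 2 passed, with miR-484 at -0.02 and miR-877-5p at 0.06. Adjusted over the list alone, these last 4 lists also gave 0, except 1 each for the miR-30 and stress-responsive lists without control 2. Of the 38 named miRNAs other than miR-7-5p, leaving out 1 library moved the log2 fold change of 27 by over 1.5 times or past 0, with a change of sign in 10. Values near 0 meet this bound by small shifts. miR-486-5p ran from -0.03 to 0.02 (SE 0.0576 as reported), while miR-142-3p ran from -0.11 to 0.17 (SE 0.0981).

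For miRNAs encoded near OIP5-AS1 in 15q15, miR-627-3p was the single one tested, at 0.06 with a 95% interval of -0.60 to 0.72, and it did not pass over all miRNAs or when adjusted over the list alone. miR-626 and miR-1282 had 0 reads, which allows up to 6.45 CPM in the shallowest library. The imprinted 14q32 cluster had 137 reads over 10 members, with 56 for miR-127-3p and 25 for miR-370-3p, and none was tested. The lists of the miR-7 strands had 1 tested member each, so that the value adjusted over the list alone equals the unadjusted one. miR-7-5p passed both ways, and miR-7-1-3p passed over the list alone but not over all miRNAs. miR-7-1-3p no longer passed over the list alone without control 2, CYRANO guide library 1 or CYRANO guide library 3.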

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

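Thinning and GC trend removal were chosen after the data were seen. miR-7-5p kept its direction and passed the threshold in all 16 alternatives run, at log2 fold changes of 1.60 to 1.81, and the log2 ratio to miR-7-1-3p stayed positive, at 1.18 or more. The count of changed miRNAs, 1 as reported, was 3 with library totals alone, with no low-count filter and with DESeq2's Wald test (miR-1908-5p, miR-3194-5p and miR-7-5p each time), 2 with a replicate block (miR-3194-5p added) and 1 to 7 with 1 library left out. The count of lists past the threshold was 0 as reported. On the reported fit it was also 0 with an estimated correlation (smallest adjusted p 0.519) and with fry (0.125). At the preset correlation it was 4 with no low-count filter (miR-17-92, erythroid, miR-15/16, miR-183 cluster), 2 with the replicate block (miR-15/16, miR-183 cluster) and 0 to 2 with 1 library left out. For these changes the cause was not tested. Replicate numbers were not taken as pairs, which required all 3 correlations to exceed 0.1. Deviations of same-numbered libraries correlated at -0.106, -0.025 and 0.047, and 1 of 6 libraries correlated best with its own number. Control 2 with CYRANO guide library 1, of unlike numbers, reached 0.177. With 3 libraries per group, these values do not exclude a batch shared by libraries of the same number. Of 603 alternative values of 38 other named miRNAs, 561 kept direction and side, 13 (5 miRNAs) passed the threshold, 29 changed sign without passing it, and 0 that passed changed sign. Another normalization moved the median log2 fold change by at most 0.03. The adjustment over all of the authors' p-values, meant for a file without counts, equals their own. Not run were pseudocounts for normalized values, since counts were used, the MIR7-2 passenger strand, not analysed here, and a list test with DESeq2, which has none. Depth limits miRNAs near 10 reads in a library, above all in control 1 with 465234 reads.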

Other observations

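The strand ratio was set in advance, but its use as a test of precursor supply, the search for other MIR7-2 and MIR7-3 strands, the thinning to equal depth and the GC correction were chosen only after the results they bear on were seen. The strands of other hairpins named next were picked after their values were seen, and none of these strands passed the threshold. miR-223-5p stood at 0.37 on the log2 scale where miR-223-3p, the abundant strand of this myeloid hairpin, stood at -0.02, a difference of 0.39 (SE 0.119). miR-486-3p stood at 0.23 where the erythroid miR-486-5p stood at 0.00, a difference (5p minus 3p) of -0.23 (SE 0.0978). The SEs of these differences take the strands of a hairpin as independent, though both were counted in the same libraries. Across 105 hairpins other than MIR7-1 with both strands tested, the median size of the difference between strands was 0.146.

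miR-7-5p was 3.2-fold higher with the CYRANO guide. With all libraries thinned to 465234 reads the log2 fold change was 1.62 (SE 0.0901). Thinning keeps the expected share of a miRNA with this many reads, so that value does not decide about depth. Without control 1, the shallowest library, the log2 fold change was 1.81 (SE 0.0841). The low depth of that library as the source is thus argued against. A higher supply of the MIR7-1 precursor as the whole cause is argued against by the log2 ratio of its strands, which was higher by 1.35 (SE 0.191), though it may add a part. Supply from MIR7-2 or MIR7-3 stays open, since 0 of their other strands were in the table used here. How the CYRANO guide itself acts on miR-7-5p was not tested. The count of 1 miRNA past the threshold was reached by 1 of the 10 splits of the 6 libraries, the real one (highest other 0), and 10 splits are too few for a share under 0.05.

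The strands of the MIR7-1 hairpin differed in log2 fold change by 1.36 (SE 0.163). A difference as large was seen in 1 of 105 other hairpins, miR-5010 at a size of 1.56 (SE 0.551). No other tested miRNA had a log2 fold change above 0.94 in size, so few hairpins had room to reach 1.36, and this count does not decide whether such differences are ordinary. The reads of miR-7-5p are a sum over up to 3 hairpins, and those of miR-7-1-3p come from 1. The SEs of 0.163 and 0.551 take the strands of a hairpin as independent, unlike the SE of 0.191 of the per-library log2 ratio.

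At an unadjusted 0.05 there were 42 miRNAs where chance gives 19.85. The authors' deposited p-values, over 1250 miRNAs with those of few reads included, gave 22, and were not counted among the 397 alone. Whether they hold such an excess is therefore not shown. The low depth of control 1 stays open: without it 36 of 408 were at that level, where chance gives 20.4, and 27 of these were among the 42, but the count passed the bound set in advance against this cause by less than its counting spread. GC content stays open: rho with the log2 fold change was -0.311, and after removal of a linear trend 36 were at that level, of which 29 were among the 42 and 7 were not, with arm GC only a stand-in for that of the mature strand. The trend could be technical or follow the guide, since its slopes (log2 per 10% GC, each relative to the mean of the 6 libraries, which fixes opposite signs of the group means) were 0.0452, 0.00751 and 0.0333 with the control guide and -0.0233, -0.0345 and -0.0282 with the CYRANO guide (exact permutation p = 0.1, the smallest possible), and library batches are not given in the sources used here. The fits without control 1 and with the GC trend removed reuse libraries of the reported fit. Much overlap of their miRNAs with the 42 is therefore built in and does not show that these repeat. The count of 42 was reached by 1 of 10 splits (highest other 25), too few splits for a share under 0.05. The count of 0 lists past the threshold was reached by 10 of 10 (highest other 2), as any split must, so this says nothing about chance.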
